A study of Glycine max with 30 samples.

How the data were processed

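Small RNA was measured in 30 libraries of mature soybean leaf from 3 RNAi lines, with transgenic (T) and non-transgenic (NT) siblings in each. Groups, lines and replicate numbers were taken from the labels. Per the labels, small RNA was size-selected on a gel, made into multiplexed libraries, pooled and sequenced on an Illumina instrument. The submitters' processing notes name Bowtie 1.1.0 as the aligner. The genome build, its annotation, the treatment of reads with several genome matches and any trimming are not given in the sources used here.

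The deposited tables have no header. The deposited read count is a whole number of reads per 100-bp bin and read length (21, 22, 23 or 24 nt), and bins without a read are not listed. The deposited RPM value is that count scaled to a single total per library, as a constant ratio within each library showed. The listed reads made up between 73.8% and 86.0% of that total. The deposited second signal is the same count scaled to a smaller reference whose nature is not given in the sources used here. Neither scaled value entered the main results, which were computed from counts.

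The soybean annotation at hand names another assembly: 15 of 20 chromosomes in the deposited tables ended before its last gene. It was not used for coordinates or gene names. Positions are 1-based and those of the deposited tables.

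The plan, written before the data were examined, scaled the libraries by a list of miRNA families and tested miRNA families, miRNA lists, distinct sequences and genes. The tables hold no sequences and no gene names, so these tests and the lists prepared for them were not used here. Stand-ins were chosen after the tables had been seen. The reference for 24-nt reads became 21-nt reads outside the RNAi-responsive regions. The library size for window tests became the effective 21-nt library, by TMM over 21-nt windows outside these regions. Windows of 1 kb with 21 and 22-nt reads took the place of genes, and bins took the place of distinct sequences. The planned main reference was the list of miRNA families. The ratio with the RNAi-responsive regions included in both 24-nt and 21-nt reads was kept as an alternative, and the report gives it where it changed a call. Windows held all listed reads, since the number of genome matches per read was not listed.

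RNAi-responsive regions were windows of 1000 bp that rose by at least 5 log2 units in T with a mean of at least 1000 CPM, joined over gaps of up to 2000 bp, and 2000 bp on either side was left out with them. A region counted as shared if another line's T mean was at least 100 CPM and at least 10 times its NT mean. This rule was also set after the data were seen.

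Single values were compared within each line by two-sided exact permutation tests of the difference of group means, with Benjamini-Hochberg values over 66 tests. Differences between lines permuted the line labels over T libraries, each taken relative to the NT mean of its line. The error of the NT means is in the SE but not in that p. Windows were tested in each line alone with the edgeR 4.0.16 quasi-likelihood test (robust), after filterByExpr with a minimum count of 10, and called at a Benjamini-Hochberg adjusted p under 0.05. Lines were compared by the interaction term. DESeq2 1.42.0 was an alternative. Other tools were R 4.3.3, limma 3.58.1, the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The floor for a group with 0 reads was 3 counts over the group. To compare numbers of bins, 24-nt reads were thinned to 15000 per library.

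The rule for named windows, set before the data were examined, took the 5 windows per direction and line with the smallest p. It was applied to 24-nt windows and to windows of 21 and 22-nt reads, which gave 60 named windows, of which a few are printed. Position classes were 5 classes of 10% of chromosome length, with distance to the nearest end of the range covered by the tables.

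The window test was tested on simulated data, with 40 windows changed by each fold. Counts were drawn from the real NT means and library sizes, with the same spread (a common dispersion) for all windows. The simulation for NRPD1 24-nt reads held 13481 windows, that for NRPDE2 1942 and that for NRPE1 8386. In these, 92.5%, 92.5% and 65% of windows raised by 2 log2 units were called, and 25%, 17.5% and 15% of windows lowered by 3 log2 units. For 21 and 22-nt reads of NRPD1, simulated over 4193 windows, 2.5% of windows raised by 2 log2 units were called. At most 0.054% of unchanged windows were called in any simulation. This rate does not cover real windows that vary more between libraries than the common dispersion allows. At these fold sizes most simulated losses were thus missed by the read filter and the test together. Lowered windows that did not pass the filter counted as missed, while raised windows could pass it through their T reads. The share missed by the test alone was not measured.

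Alternatives covered library size (all listed reads, the deposited RPM totals, the second scaling, TMM over tested windows), the filter, DESeq2, window size, the replicate number as a block, on-and-off windows, and leaving out each library in turn. A bin counted as on and off where libraries of the same group held both at least 100 RPM and at most 2 RPM. This was seen in 55 of 476 bins of 21 nt, 15 of 223 bins of 22 nt, 10 of 44 bins of 23 nt and 7 of 41 bins of 24 nt that reached the upper level. Other splits of the libraries were refitted, 10 in NRPD1 and 100 drawn at random in NRPDE2 and NRPE1.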

Results

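Small RNA libraries from mature soybean leaves were compared between transgenic plants carrying an RNAi hairpin (T) and their siblings without the transgene (NT). The hairpins were directed against NRPD1, the largest subunit of RNA polymerase IV, against NRP(D/E)2, the second subunit that polymerases IV and V share (called NRPDE2 in what follows), and against NRPE1, the largest subunit of RNA polymerase V. Both are plant polymerases that act with 24-nt small interfering RNAs in DNA methylation. The NRPD1 line was in cultivar Jack and had 3 T and 3 NT libraries. The NRPDE2 line and the NRPE1 line were in cultivar Mustang and had 6 T and 6 NT libraries each. The 3 lines shared no control libraries.

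Each library was given as reads of 21, 22, 23 and 24 nt per bin of 100 bp. The reads listed per library ranged from 2148394 to 11135361 in NRPD1 NT and from 1789260 to 2945713 in NRPD1 T. They ranged from 1231546 to 5828846 in NRPDE2 NT and from 1192015 to 3105351 in NRPDE2 T. In NRPE1 NT they ranged from 3430926 to 6823870, and in NRPE1 T from 2390208 to 11854780. Reads of 24 nt numbered between 30007 and 88819 per library in NRPDE2 T, the group with the fewest. The labels do not say from which plant each library came, so the p-values measure only the spread between these samples. With 3 against 3 libraries the exact permutation test cannot give a two-sided p below 0.1, and with 6 against 6 it cannot give one below 0.00216. The comparisons of single values formed a family of 66 tests, over which the Benjamini-Hochberg (BH) values were computed. Floors for counts of 0 cover counting error only.

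The RNAi targets were looked at first, as a check of the group labels. Gene models of the genome build used in the files were not available, so the identity of the genes in these regions was not analysed here. Regions were found instead as windows of 1 kb with a rise of at least 5 log2 units and at least 1000 CPM (reads scaled to library size) in T. In NRPD1 these lay on chromosome 1 from 54633001 to 54635000 and on chromosome 11 from 1911001 to 1913000. In NRPDE2 they lay on chromosome 4 from 4973001 to 4974000 and on chromosome 6 from 4636001 to 4638000. In NRPE1 they lay on chromosome 13 from 31061001 to 31062000 and on chromosome 15 from 44357001 to 44359000. A region on chromosome 14 from 6338001 to 6339000 rose in both NRPDE2 and NRPE1, and a region on chromosome 17 from 40464001 to 40465000 met the rule in NRPDE2 but rose also in another line, so neither was counted as a line's own.

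The own regions held 7.63% ± 2.05 (SD, n = 3) of the listed reads in NRPD1 T and 0.0243% ± 0.0211 (n = 3) in NRPD1 NT, a 314-fold difference, or 604-fold without NT replicate 1. In NRPDE2 they held 42.8% ± 2.99 (n = 6) in T and 0.0897% ± 0.0738 (n = 6) in NT, a 478-fold difference. In NRPE1 they held 33.7% ± 6.50 (n = 6) in T and 0.235% ± 0.138 (n = 6) in NT, a 143-fold difference. Every T library lay above every NT library of its line. By two-sided exact permutation tests p was 0.1 in NRPD1, 0.00216 in NRPDE2 and 0.00216 in NRPE1, the smallest value possible in each design. Reads of 21 nt made up 74.1%, 86.2% and 76.6% of the reads of these regions in T of NRPD1, NRPDE2 and NRPE1. The regions were chosen for their rise in T, so these tests describe the size of the rise and the separation of the libraries.

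**Figure D1:**
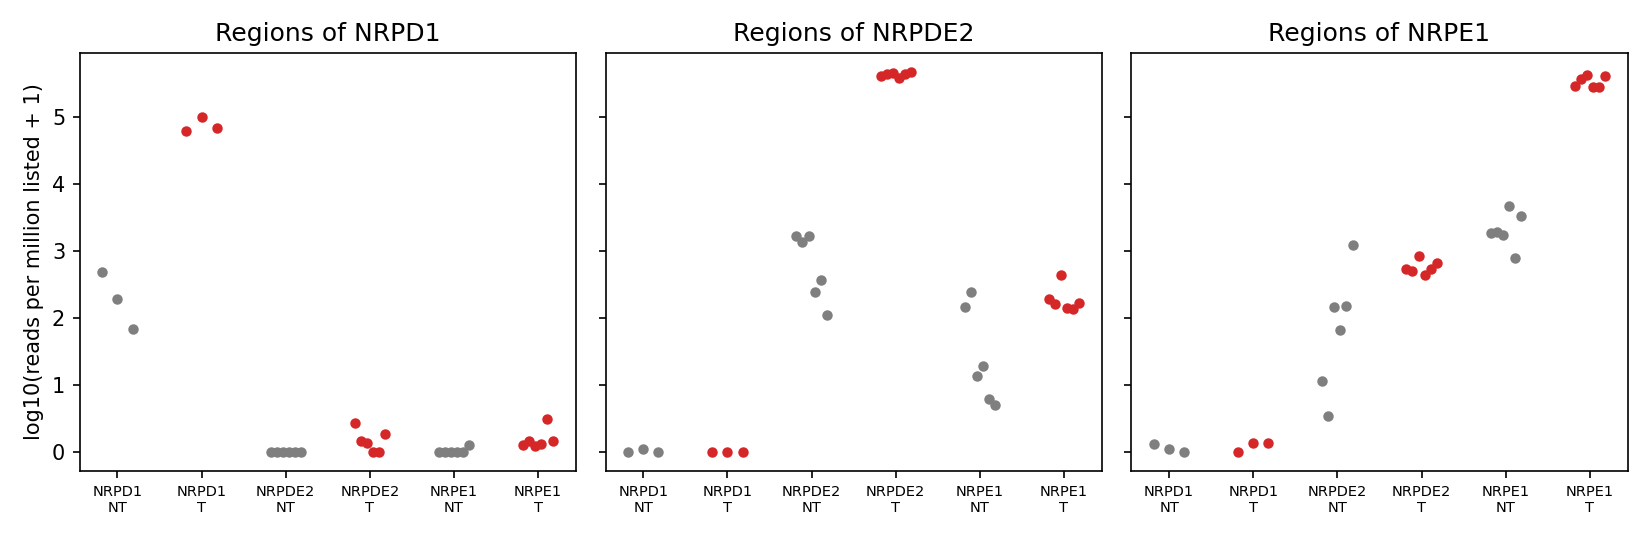
Reads of each line's own RNAi-responsive regions in all 6 groups, as log10 of CPM over listed reads plus 1, with 1 point per library (grey NT, red T). In NRPDE2 the lowest T library held 381181 CPM and the highest NT library held 1676.

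The share of 24-nt reads was compared to ask how far each subunit's RNAi lowered the small RNAs of the polymerase IV pathway. In NRPD1 it fell from 22.98% ± 1.01 (SD, n = 3) of listed reads in NT to 5.60% ± 1.06 (n = 3) in T. In NRPDE2 it fell from 11.9% ± 0.968 (n = 6) to 2.59% ± 0.328 (n = 6). In NRPE1 it fell from 14.1% ± 2.45 (n = 6) to 8.81% ± 1.11 (n = 6). The two-sided exact permutation p was 0.1 in NRPD1 (BH 0.143), 0.00216 in NRPDE2 (BH 0.00794) and 0.00216 in NRPE1 (BH 0.00794), and all T libraries lay below all NT libraries of their line. In NRPE1 part of this fall came from reads of the RNAi-responsive regions in the denominator. Outside these regions the NRPE1 share was 14.2% ± 2.44 (n = 6) in NT and 11.7% ± 1.42 (n = 6) in T, with overlapping libraries (exact permutation p = 0.0455, BH 0.12), and with bins in place of reads the NRPE1 difference was -5.15 percentage points (exact permutation p = 0.113), or -7.21 with libraries thinned to equal depth (exact permutation p = 0.0325).

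Because shares sum to 100%, 24-nt reads were also set against 21-nt reads, both outside the RNAi-responsive regions. The 24-nt reads per 21-nt read fell by 2.49 on the log2 scale in NRPD1 (SE 0.16, n = 3 and 3), a 5.62-fold loss. In NRPDE2 they fell by 2.00 (SE 0.15, n = 6 and 6), a 4.00-fold loss, and by more with other references. In NRPE1 they fell by 0.29 (SE 0.16, n = 6 and 6), and T and NT libraries overlapped. The two-sided exact permutation p was 0.1 in NRPD1 (BH 0.143), 0.00216 in NRPDE2 (BH 0.00794) and 0.110 in NRPE1 (BH 0.152). With the regions included in both 24-nt and 21-nt reads, the log2 change was -2.52 in NRPD1 (exact permutation p = 0.1), -2.67 in NRPDE2 and -1.01 in NRPE1 (exact permutation p = 0.00216 in both). Per effective 21-nt library it was -2.48, -2.59 and -0.71 (exact permutation p = 0.0108, BH 0.0357 in NRPE1), and per read behind the RPM values it was -2.24, -2.83 and -0.87. With the depositors' second reference the ratio fell by 2.81 in NRPD1, by 3.00 in NRPDE2 and by 0.61 in NRPE1 (exact permutation p = 0.0584 in NRPE1). Whether the NRPE1 result passed 0.05 thus depended on the reference, while the other lines differed in size only. With the regions included, both lengths take in reads of the own regions. These made up 46.0% of 21-nt reads in NRPE1 T, 58.0% in NRPDE2 T and 10.7% in NRPD1 T. In NT of the same lines they made up 0.403%, 0.182% and 0.0473%. Of 24-nt reads they made up 13.4% in NRPE1 T, 33.5% in NRPDE2 T and 9.13% in NRPD1 T, less than of 21-nt reads. Part of the larger change with the regions included in NRPDE2 and NRPE1 thus came from these reads. The effective library is the 21-nt total outside the regions times its TMM factor. The log2 of 21-nt reads outside the regions per effective library was 0.42 lower in T of NRPE1 and 0.59 lower in T of NRPDE2. These values reflect the TMM factor and do not measure a fall of 21-nt reads. As a share of reads outside the regions, 21-nt reads made up 44.6% in NT and 45.1% in T of NRPE1 (exact permutation p = 0.742). In NRPDE2 they made up 46.7% in both groups (exact permutation p = 0.983).

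**Figure D2:**
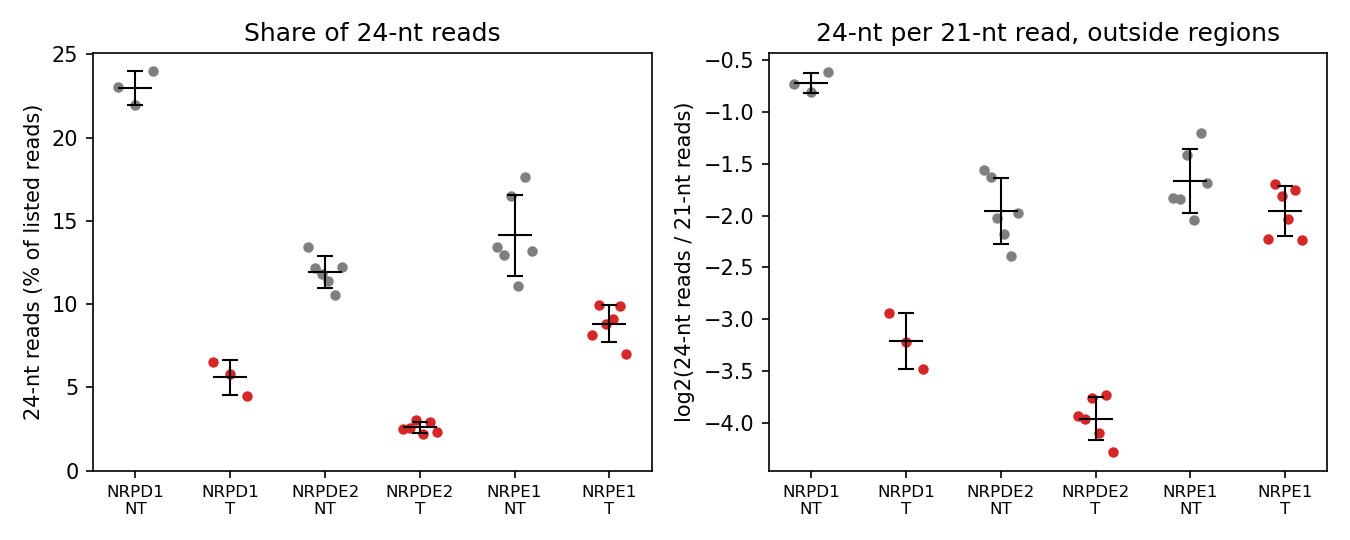
Share of 24-nt reads in percent of listed reads (left) and log2 of 24-nt reads per 21-nt read outside the RNAi-responsive regions (right), with 1 point per library (grey NT, red T) and bars for mean and SD. On the right the NRPE1 means were -1.67 in NT and -1.96 in T, while the NRPDE2 means were -1.96 and -3.96.

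The difference between lines was tested on the T libraries, each as its log2 ratio minus the NT mean of its own line. The loss in NRPE1 was smaller than in NRPDE2 by 1.71 (SE 0.22, two-sided exact permutation p = 0.00216) and smaller than in NRPD1 by 2.20 (SE 0.23, exact permutation p = 0.0119). The loss in NRPDE2 was smaller than in NRPD1 by 0.49 (SE 0.23, exact permutation p = 0.0238), but this order was not stable. With the regions included in both lengths the NRPDE2 value minus the NRPD1 value was -0.15, and per effective library it was -0.11. Its p passed 0.05 on leaving out any 1 of 7 libraries, of NRPD1 T replicate 2 (0.49) or 3 (0.36), NRPDE2 NT replicate 5 (0.41), or NRPDE2 T replicate 1 (0.49), 2 (0.49), 3 (0.45) or 5 (0.44). NRPD1 differed from the other lines in cultivar as well as in the RNAi target. Each target was represented by a single line, and how far each hairpin lowered its target was not measured. Differences between lines can thus not be told apart from the line, its set of samples or the strength of its RNAi.

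In windows of 1 kb, 24-nt reads fell at most of the sites tested in NRPD1. Of 8841 windows tested, 7962 were lower and 44 higher in T (edgeR quasi-likelihood test, BH-adjusted p under 0.05). In NRPDE2, 567 of 879 windows were lower and 105 higher by that test, and in NRPE1 2739 of 4665 were lower and 262 higher. The median log2 change over tested windows was -6.18 in NRPD1, -5.93 in NRPDE2 and -1.59 in NRPE1. With windows of 0 reads in T placed at their bound of 3 counts per group, the medians were -4.39, -4.98 and -1.59. The NRPE1 median moved in both directions with the setting. It was -0.50 with TMM over the tested windows, -0.51 without the filter and -0.95 in bins of 100 bp, but -2.19 with all listed reads as library size and -2.37 without NT replicate 4, and leaving out each library in turn it ranged from -2.37 to -1.42. The NRPDE2 median was -0.30 in bins of 100 bp, -4.24 without the filter and -7.17 without T replicate 6, and the NRPD1 median was -5.03 with TMM over the tested windows. Different numbers of windows were tested, so the counts do not rank the lines. Scaling by TMM over the tested windows gave 4747 lower and 577 higher in NRPD1, 1015 lower and 114 higher in NRPDE2, and 2894 lower and 1148 higher in NRPE1. In NRPD1 the higher windows numbered 89 with all listed reads as library size and 85 with the RPM totals. They numbered 25 with DESeq2, 10 with the second scaling and 8 with the replicate block. In NRPDE2 the lower windows numbered 949 with all listed reads as library size, 1007 with the RPM totals and 1046 with the second scaling. Without NRPD1 T replicate 1 the lower windows numbered 12125, and without T replicate 3 there were 12573 lower and 75 higher. In NRPDE2 the lower windows numbered 927 without NT replicate 4, 852 without NT replicate 6, 1169 without T replicate 1, 1120 without T replicate 2 and 1133 without T replicate 6.

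Named windows are given as CPM of the effective 21-nt library. In NRPD1 the 24-nt reads of the window on chromosome 11 from 9645001 to 9646000 fell from 213 ± 12.8 (SD, n = 3) to 2.98 ± 2.81 (n = 3), the smallest p of the line. In NRPDE2 the window on chromosome 14 from 2642001 to 2643000 had 15.2 ± 1.01 (n = 6) in NT and 0 reads in all 6 T libraries. In NRPE1 the window on chromosome 18 from 50880001 to 50881000 fell from 84.5 ± 35.2 (n = 6) to 0.252 ± 0.268 (n = 6). A window on chromosome 4 from 16719001 to 16720000 went the other way in 2 lines. It had 0 reads of 24 nt in NT and 60.0 ± 17.0 (n = 6) in T of NRPDE2, and 0.549 ± 0.514 (n = 6) in NT and 87.6 ± 32.4 (n = 6) in T of NRPE1. The edgeR adjusted p was 1.84e-11 in NRPDE2 and 3.21e-10 in NRPE1.

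Among windows that could be tested in both lines of a pair, lists of lower windows overlapped by more than independent lists would. Of the 531 lower windows of NRPDE2 that could be tested in NRPE1 too, 495 were lower there, against 326 expected from independent lists, and 0 were higher. Of the 7962 lower windows of NRPD1, 524 were tested in NRPDE2, and 503 were lower there, against 348 expected, and 5 were higher. In NRPE1 3118 of them were tested and 2250 (72.2%) were lower, against 1968 expected, and 13 were higher. Only 2289 of the 3627 windows tested in both NRPD1 and NRPE1 were lower in NRPE1, and 98.3% of those were lower in NRPD1. The overlap thus lay near its upper limit. The interaction of transgene and line was tested with edgeR in each pair. Between NRPDE2 and NRPE1 the log2 change was higher in NRPE1 at 3228 of 7617 windows and lower at 23. DESeq2 gave 2825 and 20.

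At the windows that lost 24-nt reads in NRPD1, the other lengths fell too. Their 24-nt reads fell 43.0-fold, 23-nt reads 13.4-fold, 22-nt reads 3.44-fold and 21-nt reads 3.05-fold (n = 3 and 3, each with the exact permutation p of 0.1). At the lower windows of NRPDE2 the losses were 13.6-fold, 4.45-fold, 2.50-fold and 2.24-fold, and at those of NRPE1 6.81-fold, 4.33-fold, 2.92-fold and 2.16-fold (n = 6 and 6, each with an exact permutation p of 0.00216). These folds are of reads summed over windows whose make-up differed. In NT, 24-nt reads made up 70.6% of their reads in NRPD1, 3.70% in NRPDE2 and 19.3% in NRPE1. Reads of 21 nt made up 10.0%, 91.5% and 62.9%, so the folds do not compare the lines at like sites. The windows were chosen for their 24-nt loss, so the first value of each line is inflated by that choice. In NRPE1 the 22-nt reads were lower at windows called neither way as well, 1.36-fold, and so were the 21-nt reads, 1.47-fold (exact permutation p = 0.0108 and 0.0152), while the 23-nt difference of 1.56-fold did not pass 0.05 (exact permutation p = 0.0606). In NRPDE2 the same differences were 1.25-fold, 1.07-fold and 1.39-fold, none past 0.05 (exact permutation p = 0.134, 0.206 and 0.0671). A bin on chromosome 20, named below, lay in these windows. It alone held 54.6% of 22-nt and 64.2% of 23-nt reads outside the regions in NRPE1 NT, and 64.3% and 63.5% in NRPDE2 NT. The 22-nt and 23-nt folds thus rest largely on this bin and do not show a fall across these windows. The 24-nt reads that stayed came from fewer places in NRPD1 and NRPDE2. Thinned to equal depth, they lay in 12670 ± 118 bins (SD, n = 3) in NRPD1 NT and 4800 ± 284 (n = 3) in T. In NRPDE2 they lay in 13138 ± 217 (n = 6) and 4853 ± 880 (n = 6), and in NRPE1 in 13415 ± 262 (n = 6) and 12688 ± 621 (n = 6). The exact permutation p was 0.1 (BH 0.143), 0.00216 (BH 0.00794) and 0.0216 (BH 0.0649). The 10 most abundant bins held 8.57% ± 0.222 (SD, n = 3) of 24-nt reads in NRPD1 NT and 40.6% ± 1.61 (n = 3) in T (exact permutation p = 0.1, BH 0.143). They held 4.75% ± 1.12 (n = 6) and 28.7% ± 5.89 (n = 6) in NRPDE2 (exact permutation p = 0.00216, BH 0.00794). In NRPE1 they held 3.39% ± 0.970 (n = 6) and 5.05% ± 1.77 (n = 6), a difference that did not pass 0.05 (exact permutation p = 0.0693, BH 0.143). The bin on chromosome 20 from 37447401 to 37447500 alone held 7.19% ± 0.346 (n = 3) of the 24-nt reads of NRPD1 NT and 33.5% ± 1.32 (n = 3) in T. Most of the rise of the 10 most abundant bins in NRPD1 thus lay in this bin. It also held 65.6% of the 23-nt reads outside the regions in NRPD1 NT and 78.1% in T.

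Reads of 21 and 22 nt were counted together in 1-kb windows to ask whether shorter small RNAs changed as well. In NRPDE2, 627 of 2247 windows were higher and 384 lower in T, and in NRPE1 793 of 4793 were higher and 783 lower (edgeR, BH-adjusted p under 0.05). The balance of directions depended on the scaling. In NRPDE2, 550 were higher and 546 lower with all listed reads as library size, 549 and 582 with the RPM totals, 561 and 535 with TMM over the tested windows, and 390 and 480 with the second scaling. In NRPE1, 658 were higher and 979 lower with all listed reads, 635 and 930 with the RPM totals, 767 and 813 with TMM over the tested windows, and 588 and 431 with the second scaling. In NRPD1 27 of 3726 windows were higher and 211 lower by edgeR. DESeq2 gave 52 higher and 258 lower in NRPD1, while edgeR gave 30 and 113 with all listed reads, 33 and 149 with the RPM totals, 31 and 168 with TMM over the tested windows, and 22 and 339 with the second scaling. The NRPD1 edgeR calls rested on all 6 libraries: the count was 0 in both directions without any 1 of them, with 468, 484 and 599 windows at an unadjusted p under 0.05 without NT replicates 1, 2 and 3, and 800, 628 and 918 without T replicates 1, 2 and 3. It was also 0 in both directions with the replicate block, without the filter and in bins of 100 bp. As a background, the NT libraries of NRPE1 and NRPDE2 differed at 15 windows lower and 57 higher in NRPE1 of 4325 by edgeR, and at 55 and 369 by DESeq2.

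In NRPE1 the window with the smallest p among those that rose lay on chromosome 12 from 38342001 to 38343000. It went from 7.93 ± 2.35 (SD, n = 6) to 1898 ± 640 (n = 6) CPM for reads of 21 and 22 nt. In NRPDE2 3 adjoining windows on chromosome 19 from 9581001 to 9584000 rose together, from at most 0.305 ± 0.746 (n = 6) in NT to between 632 ± 236 and 1018 ± 295 (n = 6) in T. The window on chromosome 13 from 41592001 to 41593000 had 29.0 ± 2.65 (n = 3) in NRPD1 NT and 0 reads in NRPD1 T.

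Of the windows tested in both Mustang lines, 549 were higher in NRPDE2 and 240 in NRPE1, and 184 were higher in both, in 121 separate places, against 61.6 expected from independent lists. At these 184 windows 22-nt reads rose 8.97-fold in NRPDE2 T and 4.72-fold in NRPE1 T, and 24-nt reads rose 7.90-fold and 6.37-fold (n = 6 and 6, each with an exact permutation p of 0.00216, on windows chosen for their rise in 21 and 22-nt reads). In NRPD1 T the 22-nt reads of these windows were 0.843 times and the 24-nt reads 0.713 times the NT level (n = 3 and 3, exact permutation p of 0.3 and 0.2). Of the 184 windows, 179 had a 24-nt read in NRPDE2 and 183 in NRPE1, and the mean 24-nt level was higher in T at 165 and 171 of them. Of all 627 gained windows of NRPDE2, 97 passed the filter for 24-nt reads, which high 24-nt reads in T help to pass, and 83 of these were higher and 2 lower in 24-nt reads, against 20 and 18 of 202 windows called neither way. Of all 793 gained windows of NRPE1, 109 passed, and 82 were higher and 5 lower, against 174 and 90 of 749. Windows that lost 21 and 22-nt reads and passed the 24-nt filter were mostly lower in 24-nt reads too. This held for 197 of 197 in NRPD1, 45 of 62 in NRPDE2 and 357 of 391 in NRPE1. Among windows called neither way it held for 269 of 1102, 18 of 202 and 90 of 749.

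Position along the chromosomes was compared last, a comparison added after the data were seen. In NRPE1 the 24-nt loss was larger near chromosome ends: in the outermost 10% of chromosome length on either side the log2 change was -1.01 (SE 0.25), and in the innermost class, 40% to 50% from the nearest end, it was -0.39 (SE 0.26). The log2 ratio of outer to inner reads was 0.98 ± 0.07 (SD, n = 6) in NRPE1 NT and 0.36 ± 0.17 (n = 6) in T, a change of -0.62 (two-sided exact permutation p = 0.00216), with 6 of 6 T libraries below all NT libraries. In NRPDE2 the change was -0.10 (n = 6 and 6, exact permutation p = 0.119), or -0.14 without T replicate 3 (exact permutation p = 0.0195). In NRPD1 it was -0.36 (n = 3 and 3, exact permutation p = 0.1), with 3 of 3 T libraries below all NT libraries. The NRPE1 change minus the NRPDE2 change was -0.52 (SE 0.09, exact permutation p = 0.00216), and the NRPE1 change minus the NRPD1 change was -0.26 (SE 0.12, exact permutation p = 0.0714). The most abundant bin was left out of these ratios. Without the 129 windows that held 0.5 of the remaining 24-nt reads of NRPDE2 T, the change was -0.20 in NRPDE2 (exact permutation p = 0.00433), -0.44 in NRPD1 and -0.73 in NRPE1 (exact permutation p = 0.00216), and NRPE1 minus NRPD1 was -0.29 (SE 0.14, exact permutation p = 0.0476). Counted as windows called lower by edgeR, the outermost class exceeded the innermost in all 3 lines, with 68.1% and 47.6% of tested windows in NRPDE2, 62.3% and 45.1% in NRPE1, and 91.3% and 82.0% in NRPD1.

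**Figure D3:**
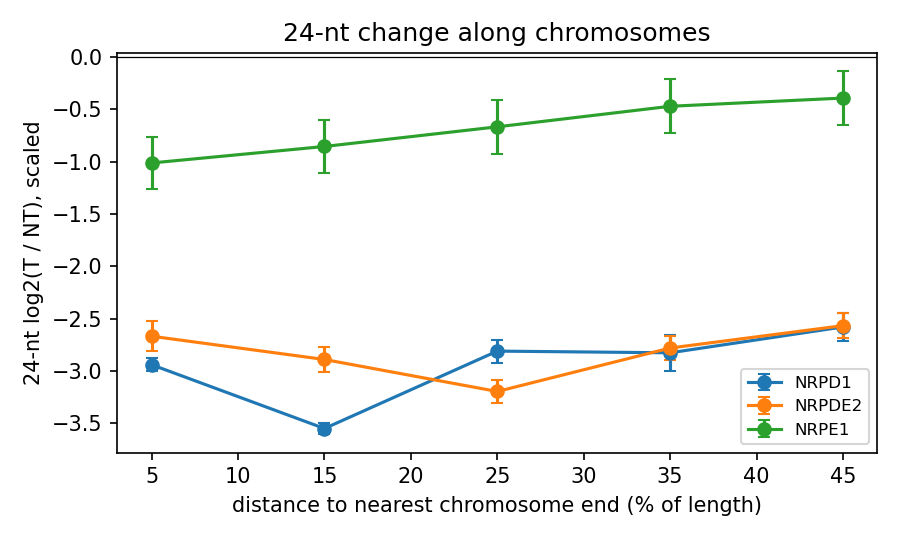
Log2 change of 24-nt reads (T over NT, per effective 21-nt library) in 5 classes of distance to the nearest chromosome end, in percent of chromosome length, with bars for the standard error. In NRPE1 the change ran from -1.01 in the outermost class to -0.39 in the innermost.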

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

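The tests in this part were chosen after the result was seen, except for the position profile of reads in the RNAi-responsive regions, the count of chromosomes with a shift below 0 and the position shift without the most abundant windows. The tests of library size and of 24-nt loss at shared gained windows replaced earlier ones, since the choice of windows or the filter on read number shaped their outcome.

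Among 36 checks for a library far from the others of its group, 2 passed, close to the 1 in 20 that chance gives. NRPDE2 T replicate 6 had 6547 bins with a 24-nt read at equal depth, while the next library had 4990. NRPE1 T replicate 6 had a log2 of 24-nt reads per effective library of -2.69, while the next lay at -2.17. No explanation was tested for either.

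The 24-nt change was smaller in NRPE1 than in the other lines. The NRPE1 effect minus the NRPD1 effect was 2.20 and the NRPE1 effect minus the NRPDE2 effect 1.71, on the log2 scale and tested by permuting line labels. The NRPDE2 effect minus the NRPD1 effect was 0.49 by that test. But it was -0.15 with the regions included in both lengths, -0.11 per effective library and -0.18 with the second reference. Leaving out any 1 of 7 libraries also raised its p above 0.05, so no order of these lines is claimed. The edgeR interaction called 3251 windows of 24-nt reads and 376 of 21 and 22-nt reads between NRPE1 and NRPDE2. Between NRPDE2 and NRPD1 it called 76 and 378, and between NRPE1 and NRPD1 it called 7508 and 604. NRPD1 was in another cultivar, and cultivar and target cannot be separated there. In all pairs, target cannot be separated from line, sample set or strength of the RNAi, which was not measured. The position shift of NRPE1 minus that of NRPDE2 was -0.52.

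Reads of each line's own RNAi-responsive regions also appeared in NT libraries and in libraries of other lines. A candidate explanation is carry-over of reads between libraries. NRPDE2 libraries held the NRPE1 regions at 0.125% of the NRPE1 T level, while NRPD1 libraries held them at no more than 6.80e-05%. NRPD1 was in cultivar Jack and the other lines in Mustang, so this contrast cannot be told apart from cultivar. The profile of NT reads over bins followed that of T reads, with a lowest correlation of 0.925 over the 3 lines (across bins, which are not independent). Small RNAs made in NT siblings could give the same profile, so it cannot separate them from carry-over. Small RNAs made in NT siblings remain open, since NRPE1 NT held these regions at 8.95 times the level of NRPDE2 NT (31.9 times without NRPDE2 NT replicate 6), and both explanations allow that.

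The 184 windows with more 21 and 22-nt reads in T of both NRPDE2 and NRPE1 form a further pattern. Carry-over between the T libraries of these lines is unlikely as the whole cause, since the lower T level was at a median 71.2% of the higher. A simple exchange of 24-nt for shorter reads is also argued against, because the mean 24-nt level was higher in T at 92.2% of those with a 24-nt read in NRPDE2 and at 93.4% in NRPE1. The choice of library size stays open in part: with all listed reads, 136 of the 184 windows, or 73.9%, were still called higher in both lines. An effect of RNAi against NRPE1 and NRPDE2, or of hairpin expression itself, was not tested and stays open.

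The larger 24-nt loss near chromosome ends in NRPE1 was weighed last. A difference in read level is argued against, since in each of 4 classes of equal size by read level windows of the outermost class were called lower more often than those 30% to 50% from the nearest end, by at least 13.6 percentage points. A few chromosomes are argued against, since 19 of 20 had a shift below 0, and so are a few abundant windows in NRPDE2 T, without which NRPE1 minus NRPDE2 was -0.53. A stronger dependence on the largest polymerase V subunit near the ends is a possible explanation, with an exact permutation p of 0.00216 against NRPDE2, but the gap in windows called lower, outermost minus innermost class, was 20.6 percentage points in NRPDE2 and 17.3 in NRPE1. An end-biased loss that is not particular to NRPE1 stays open too, since the NRPD1 shift was -0.36 in the same direction and NRPE1 minus NRPD1 was -0.26 (exact permutation p = 0.0714), or -0.29 without the abundant windows (exact permutation p = 0.0476).

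Other splits of the libraries were refitted for each count of called windows, in both directions together. In NRPDE2, 1 of 100 splits, the real one, called as many windows, with 672 windows of 24-nt reads against 0 in any other split and 1011 windows of 21 and 22-nt reads against at most 1. In NRPE1 1 of 100 did so likewise, with 3001 and 1576 windows against at most 1. A chance division of these libraries is thus an unlikely source of these 4 counts, but it is not excluded. The value of 1 in 100 is the smallest share that 100 splits can give. The other splits also mixed T and NT libraries, which widens the spread within groups and can lower their counts. In NRPD1 only 10 splits exist, so the share cannot go under 0.1. The real split called 8006 and 238 windows and the highest other split called 0 by edgeR.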

How the results depend on the processing

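Settings chosen after the data were seen were the RPM totals, the second scaling, the effective library as reference, bins in place of reads, bins of 100 bp, removal of on-and-off windows, smaller windows for 21 and 22-nt reads, and leaving out the regions or the most abundant bin. The other settings were planned. Over settings other than leave-one-out, 127 of 184 values kept their direction and side of the threshold (counts, within 1.5 times), and 3 reversed. The cause was not tested where none is given.

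The NRPD1 and NRPDE2 24-nt losses in share and ratio kept their direction in all settings run, and in NRPDE2 p stayed under 0.05 (exact tests). The NRPDE2 log2 ratio was -2.67 with the regions, -2.59 per effective library and -2.83 per read behind the RPM values. The NRPE1 share difference was -3.49 points (p = 0.0844, exact permutation) without the regions and the most abundant bin, and for bins -5.15 (p = 0.113, exact permutation), or -7.21 at equal depth (p = 0.0325, exact permutation). The NRPE1 log2 ratio was -1.01 with the regions, -0.71 per effective library and -0.87 per read behind the RPM values, all then past the threshold. NRPDE2 minus NRPD1 reversed to -0.15 with the regions, -0.11 per effective library and -0.18 with the second reference.

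Leaving out each library in turn, the share difference ranged from -17.9 to -16.8 points in NRPD1, -9.63 to -9.04 in NRPDE2 and -5.93 to -4.62 in NRPE1. The log2 ratio ranged from -2.63 to -2.36, -2.09 to -1.92 and -0.36 to -0.19. The differences between lines ranged from 0.36 to 0.63 (NRPDE2 minus NRPD1), 2.07 to 2.34 (NRPE1 minus NRPD1) and 1.63 to 1.81 (NRPE1 minus NRPDE2). Lower 24-nt windows ranged from 7873 to 12573, 627 to 1169 and 2647 to 4101 in NRPD1, NRPDE2 and NRPE1, and higher ones from 37 to 75, 97 to 152 and 241 to 291. For 21 and 22-nt reads, lower windows ranged from 342 to 495 in NRPDE2 and 813 to 1008 in NRPE1, and higher ones from 577 to 796 and 731 to 1149. In NRPD1 they were 0 to 0 in both directions by edgeR, with 468 to 918 at an unadjusted p under 0.05. DESeq2 with all libraries called 258 lower and 52 higher.

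With all listed reads as library size, NRPD1 had 89 higher 24-nt windows and 113 lower windows of 21 and 22 nt, and NRPDE2 had 949 lower 24-nt windows. The RPM totals gave 85 higher (NRPD1, 24 nt), 1007 lower (NRPDE2, 24 nt) and 582 lower (NRPDE2, 21 and 22 nt). TMM over tested windows gave 4747 lower and 577 higher (NRPD1, 24 nt), 1015 lower (NRPDE2, 24 nt) and 1148 higher (NRPE1, 24 nt). The second scaling gave 10 higher (NRPD1, 24 nt), 339 lower (NRPD1, 21 and 22 nt), 1046 lower (NRPDE2, 24 nt), 390 higher (NRPDE2, 21 and 22 nt) and 431 lower (NRPE1, 21 and 22 nt).

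Without the filter more windows were tested. Lower and higher 24-nt windows were then 59745 and 106 in NRPD1, 46453 and 730 in NRPDE2, and 25484 and 3172 in NRPE1. Those of 21 and 22 nt were 17499 and 6033 in NRPDE2, 12686 and 8238 in NRPE1, and 0 and 0 in NRPD1 by edgeR, with 11478 at an unadjusted p under 0.05. Bins of 100 bp hold fewer reads each. They gave 3995, 180 and 1083 lower for 24 nt in NRPD1, NRPDE2 and NRPE1, 65 higher for 24 nt in NRPDE2, 1179 higher for 21 and 22 nt in NRPDE2, and 0 and 0 for 21 and 22 nt in NRPD1 by edgeR, with 375 at an unadjusted p under 0.05.

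DESeq2 gave 25 higher 24-nt windows in NRPD1. Between the NT groups it gave 55 lower and 369 higher windows of 21 and 22 nt. Its interaction counts, lower and higher in the line named first, were 216 lower for 21 and 22 nt (NRPE1 against NRPDE2), 24 and 154 for 24 nt and 244 and 626 for 21 and 22 nt (NRPDE2 against NRPD1), and 158 lower for 24 nt with 253 and 886 for 21 and 22 nt (NRPE1 against NRPD1).

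Replicate numbers did not clearly pair the samples. Correlations of same-numbered libraries ranged from -0.20 to 0.20, and at most 3 of 6 correlated best with their own number. That count was reached for 21 and 22-nt windows of NRPDE2, with a mean of 0.068 against -0.014 for other numbers. A weak pairing is thus not excluded there. With the replicate block, NRPD1 had 8 higher and 7872 lower 24-nt windows, and 0 and 0 of 21 and 22 nt by edgeR (359 at an unadjusted p under 0.05). The block left the mean differences at -17.4, -9.35 and -5.32 points and the log2 ratios unchanged (-2.49 in NRPD1, -0.29 in NRPE1), with sign-flip exact p of 0.25 in NRPD1, the smallest possible. It changed no other call.

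Of 1074 values for the 60 named windows, 989 were unchanged in direction and call, 85 lost the call and 0 reversed by edgeR or DESeq2. Among listed reads, all lengths and 20 to 24 nt give the denominator used, since 21 to 24 nt are listed. With the reads behind the RPM values, whose lengths are not listed, as denominator the share differences were -13.9, -7.63 and -4.29 points in NRPD1, NRPDE2 and NRPE1, with calls unchanged. Settings that need sequences or numbers of genome matches were not run, nor was a fit of all 6 groups for miRNA families. A group with 0 reads in a window allows up to 3 counts, which limits the size of loss that depth can show.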
